A study of Theobroma cacao with 36 samples.

How the data were processed

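Messenger RNA libraries from cacao cell suspensions were sequenced as single-end reads, per the labels' protocols. The tools named by the authors are HISAT2, kallisto and DESeq2, per the submitters' processing notes. Their roles, their versions and the genome build are not given in the sources used here. The 2 deposited tables list the same number of genes, one with whole-number counts and one that the authors normalized, per its file name.

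Sample groups were taken from the titles. Each table's column headings were compared with every sample's title and description, after removing punctuation and case. All 36 columns of per-sample values in either table matched no label and were not used. Assigning them by their order, their number or their values would have been a guess about the treatment of each culture. The light against dark, day 0 and between-day tests fixed beforehand, their alternatives and the gene lists were consequently not run. Gene identifiers were compared with every field of a RefSeq gene table of the Criollo assembly, and 0 of 24831 matched. That gene table held no symbol, locus tag or synonym of the form that the identifiers take. Both match counts were recomputed under other matching rules, added after seeing the data.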

Results

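RNA sequencing was carried out on cell suspension cultures of cacao (Theobroma cacao), the tree whose seeds give cocoa. Per the labels, 36 samples fell into 9 groups of 4 replicates. Dark-grown cultures were sampled on days 0, 1, 7, 8 and 14, and LED-illuminated cultures on days 1, 7, 8 and 14. The illuminated cultures received light for part of each day and darkness for the rest, per the labels. Per the labels' treatment protocol, the light arm received white light up to day 7 and blue light afterwards. The sample titles name white light on days 8 and 14 as well, and this difference was not resolved. Fresh medium was added on day 7 in both arms, so within the light arm the change of light coincided with this addition. The dark arm received the medium without a change of light. The study asked how gene expression differed between illuminated and dark cultures over this time course.

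Both processed tables held 36 columns of values over 24831 gene identifiers. The columns were headed by sample numbers that did not stand in numerical order. Of the 36 headings, 21 held a plain number and 15 a number followed by a suffix of letters or a further number. The labels named the samples by treatment, day and replicate. Of the 36 columns in either table, 0 matched a label. From the labels alone, no column could be assigned to a treatment, a day or a replicate. No other key to the columns was tried, and one that pairs them with the titles would be needed. The reference gene table, which gave no product names, matched 0 of the 24831 identifiers, so no gene was named here. No other annotation was tried, and one keyed to these identifiers would be needed. Because the labels assigned no column to a group, the values were not analysed here. None of the 16 comparisons set out before the data were examined was made, and no expression level, fold change or count of changed genes is reported.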

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

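The alternatives set out before the data were examined (normalisation, filter, test, samples in the fit, block and leaving out replicates) were not run, since no expression comparison was made. No paired analysis was possible because the columns of the tables carry no replicate number that the labels share. The numbers in the headings are sample numbers, and none was marked as a replicate, although some also occur in the titles. Whether equal replicate numbers in different groups mark a shared culture was not established here. The counts of matched columns and matched gene identifiers were recomputed under other matching rules, all chosen after seeing the data. The number of columns that matched a single sample was 0 with exact headings, 0 with every label field searched, protocols included, and 0 when a heading and a title needed only to share a number. Under that last rule 23 of the 36 headings shared a number with no title, and the other 13 shared one with 8 to 15 samples each. Every number in the titles occurs in several of them, so that rule could not single out a sample. Exact headings were stricter than the main rule, which had matched no column, so their result was also fixed beforehand. The number of gene identifiers matched was 0 with case and punctuation removed and 0 with the annotation version removed. The reference named genes in another form, so neither change could have produced a match. These rules test the matching alone and say nothing about expression.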
